A study of Homo sapiens with 2 samples.

How the data were processed

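Single-cell RNA of H1 human embryonic stem cells was measured in 1 WT and 1 ZNF263 homozygous KO library. Per the labels' protocols, cells were dissociated, stained for viability and captured with barcoded beads in microwells, and complementary DNA of polyadenylated RNA was amplified and fragmented with Tn5. The authors deposited UMI counts per gene and barcode, as whole numbers with no normalization. The submitters' processing notes name UMI-tools 1.1.2, STAR 2.7.10a, featureCounts 2.0.1, Subread and the genome build hg38, with no role or order; the gene annotation and any filter on barcodes are not given in the sources used here. Barcodes in the deposited count tables ranged down to 1 UMI. The KO table held 15 more entries than its size line states and all were used. The libraries list 31082 and 30050 genes, of which 27540 are in both, under symbols that were taken as given. Chromosomes and coordinates are from the RefSeq gene table of the same genome build (GRCh38).

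A barcode was kept as a cell with at least 1000 UMIs, at least 500 genes and at most 20% UMIs of mitochondrially encoded genes. This kept 0.348% of WT and 0.272% of KO barcodes. The histogram of UMIs per barcode had its low point between 100 and 126 UMIs in both libraries, and 137863 WT and 125459 KO barcodes lay at or above 100 UMIs, so the kept cells are the deepest part of the barcodes that may hold cells. Doublets were not removed for the values reported. Scrublet, run through Scanpy 1.11.5, marked 1 WT and 8 KO cells, too few for its calls to be used, and an alternative left out the 5% of cells with the highest scores and cells over 4 times the median UMI count.

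UMIs were summed over kept cells and scaled to CPM, with exact Poisson intervals for levels and exact conditional binomial intervals for ratios. Shares have exact Clopper-Pearson intervals. Intervals of levels, ratios and shares cover counting error only. Those of medians over genes are order-statistic intervals that reflect the spread between genes. None of them holds variation between cultures, clones or libraries. No p-value, standard error or count of changed genes was computed, because cells of 1 library are not replicates. For comparisons across cells each cell was thinned at random to 1000 UMIs, which left out 0 kept cells. Variance over mean was computed for genes with a mean of at least 0.1 UMI per thinned cell in both libraries. Clusters were found by the Leiden method (leidenalg 0.10.2, python-igraph 0.11.9) at resolution 0.5 on 30 principal components and 15 neighbours, from 2000 variable genes without mitochondrially encoded and ribosomal protein genes, each centred within its library. The distance between cluster shares is the sum of the percentage points by which KO shares exceeded WT shares. Cell cycle scores set each list against genes of the same expression bins, with a limit of 0. Control genes were first drawn at random. All genes of a bin were used instead after the draw was seen to move the shares. The range over 15 combinations of a thinning draw and a control gene draw is given, with thinning draws shared between combinations. NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

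The gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. There were 30 written lists and 2 lists by symbol pattern. Of 684 list entries, 665 matched a symbol, 6 matched through another symbol of the same gene and 13 did not match. Members with a mean of at least 5 CPM counted as measured, and medians have exact order-statistic intervals. The primitive streak, endoderm, mesoderm, amnion and trophoblast, and naive-state lists had fewer than 3 measured members and have no median here. Genes were named if they were ZNF263, POU5F1, NANOG or SOX2; if they had the 12 highest or 12 lowest ratios at a mean of at least 20 CPM with the same direction under each scaling and cell filter planned; if they had up to 4 of the largest ratios of a list at a mean of at least 10 CPM; or if they had the 5 largest differences in variance over mean at either end. The 5 leading genes of a cluster describe it and are not results. X-inactive specific, Y-linked and, for the highest and lowest ratios, mitochondrially encoded genes were left out. Other genes named were chosen after their values were seen: TUBB3 and LHX2 as members within 1.5-fold, TAF9 and the neighbouring genes as paralog and surroundings of TAF9B, and the genes of the CRABP1-rich cells.

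The functions were tested on simulated data made from the WT profile at the depths of the 2 libraries. A ZNF263 KO against WT comparison was simulated with 50 genes at each fold. The intervals held the true ratio for 90% of genes at 0.25-fold, 98% at 0.5-fold and 96% at both 2-fold and 4-fold. For 5700 genes with no change they held it for 95.2%. The summed counts were drawn from a Poisson distribution, the model behind the intervals. The coverage therefore does not address genes whose counts vary more than that between cells. Between random parts of the WT cells, with 1467 cells in the smaller part, 6 of 6 lineage share intervals and 3 of 3 cell cycle intervals held 0, and the distance between cluster shares was 2.81 percentage points.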

Results

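The data were single-cell RNA counts from H1 (WA01), an established human embryonic stem cell line, in an unedited wild-type (WT) form and in a form in which both copies of ZNF263, a zinc finger transcription factor, were knocked out (KO) with Cas9. Each genotype was measured in 1 library, made by a microwell method in which polyadenylated RNA of single cells is captured on barcoded beads. The WT library held 60578040 unique molecular identifiers (UMIs) over 842407 barcodes and the KO library 54559376 over 841049. Most barcodes held few UMIs. A minimum of 1000 UMIs and 500 genes and at most 20% mitochondrial UMIs left 2935 WT cells with a median of 1328 UMIs and 2286 KO cells with a median of 1289.5 UMIs, which together hold 7.68% of the WT UMIs and 6.54% of the KO UMIs. With 1 library per genotype there is no replicate check and no test between the genotypes, so values of both libraries are given. All intervals are 95% intervals. They cover counting error only, except those of medians over genes, which reflect the spread between genes.

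The first comparison was of the targeted gene. ZNF263 (chromosome 16, 3283491 to 3301401, hg38) was lower in the KO library, at 7.57 CPM (UMI counts scaled to the library total; 27 UMIs, interval 4.99 to 11.01), than in the WT library, at 17.8 CPM (83 UMIs, interval 14.2 to 22.1), a ratio of 2.36-fold (interval 1.51 to 3.79). After each cell was thinned to 1000 UMIs, 1.67% of WT cells (interval 1.24% to 2.20%) and 0.875% of KO cells (interval 0.535% to 1.35%) held a ZNF263 UMI, against 2.76% and 1.18% without thinning. The labels do not say which part of the gene was deleted, so remaining tags neither support nor contradict the KO label.

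The second comparison asked which genes differed between the KO and the WT populations. POU3F2, a neural POU-domain transcription factor, was 11.6-fold lower in the KO library (13 against 197 UMIs, interval 6.64 to 22.2). WLS, which carries WNT ligands to the cell surface, was 9.82-fold lower (interval 6.72 to 14.9), NR2F1, an orphan nuclear receptor of the developing nervous system, 6.20-fold lower (interval 4.05 to 9.91), FST, the activin antagonist follistatin, 6.15-fold lower (interval 5.29 to 7.19), and PRTG, the cell surface protein protogenin, 5.36-fold lower (interval 4.65 to 6.22). CDH1, the epithelial cadherin, was 3.09-fold higher in the KO library (275 against 116 UMIs, interval 2.48 to 3.87), and CLDN7, a tight junction claudin, 2.20-fold higher (interval 1.72 to 2.84).

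The lowest ratio belonged to TAF9B, which encodes a TATA-box binding protein associated factor (chromosome X, 78129748 to 78139650). It held 4 UMIs in the KO library and 201 in the WT library, a 38.6-fold difference with an interval of 14.8 to 143. The 10 measured genes nearest to it, 5 on each side, had a median log2 ratio of -0.08 (interval -0.52 to 0.31). They lay between 76173062 and 81298547 and went both ways. The nearest on each side, PGK1 and LPAR4, were lower, at -0.52 and -0.58. The next on each side, COX7B and ITM2A, were higher, at 0.31 and 0.66. TAF9, the paralog of TAF9B, held 2 UMIs in the KO library and 0 in the WT library, too few to compare. The other genes among the 12 lowest were STMN2, a neuronal stathmin, at 4.92-fold lower, TSPAN18 at 3.94-fold, EFNB2, the ligand ephrin-B2, at 3.73-fold, MACROH2A2, a histone variant, at 3.55-fold, the homeobox gene NKX1-2 at 3.53-fold and the tetraspanin CD82 at 3.49-fold. At the high end, RCC2 was 3.04-fold higher (1016 against 435 UMIs, interval 2.72 to 3.41), RAVER1, an RNA-binding protein, 2.60-fold, LCK, a SRC-family kinase, 2.52-fold, PLPP2, a phospholipid phosphatase, 2.42-fold, LPAR3, a lysophosphatidic acid receptor, 2.38-fold, NMRK2, a nicotinamide riboside kinase, 2.27-fold and CFAP95 2.24-fold. The 12 highest also held LOC105372310 (3.02-fold) and the pseudogenes NONOP1 (2.68-fold) and HMGN2P41 (2.39-fold), whose counts are uncertain because a pseudogene can share reads with its parent gene.

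Across 5710 genes with a mean of at least 20 CPM, the log2 ratios of KO over WT had a median of -0.12, and the central 95% of them ran from -0.78 to 0.54. The median half-width of a single gene's counting interval was 0.29. Ribosomal protein genes together held 218921 CPM in the WT library and 242702 CPM in the KO library. Medians of the main gene lists are also given relative to the median of all genes.

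**Figure D1:**
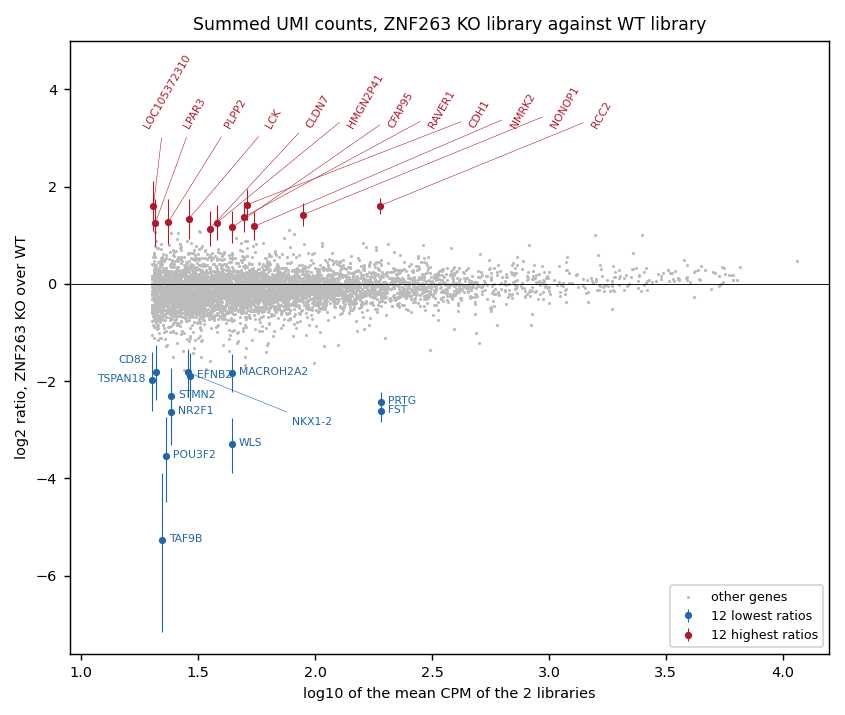
Log2 ratio of KO over WT summed UMI counts (vertical axis) against the log10 mean CPM of both libraries (horizontal axis) for genes with a mean of at least 20 CPM, 1 point per gene. Blue and red points are the 12 lowest and 12 highest named genes with 95% counting intervals; TAF9B is the lowest, and CDH1 is the highest at 3.09-fold.

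The pluripotency factors differed less than these genes. SOX2 was at 321 CPM in the WT library (interval 305 to 338) and 292 CPM in the KO library (interval 275 to 310). NANOG was at 14.8 CPM (interval 11.5 to 18.8) and 18.5 CPM (interval 14.3 to 23.5), and the interval of its log2 ratio, -0.19 to 0.83, included 0. POU5F1 was at 50.1 CPM and 77.1 CPM, 1.54-fold higher in the KO library (interval 1.29 to 1.84), and is reported as uncertain because its processed pseudogenes can share its reads. Of the 19 measured members of the core pluripotency list, 14 lay within 1.5-fold. In the KO library 4 were at least 1.5-fold higher and 1 was at least 1.5-fold lower. By direction alone, 10 members were higher and 9 lower. TDGF1, the NODAL co-receptor, had a log2 ratio of 0.81 (interval 0.67 to 0.96), DNMT3B, a DNA methyltransferase, 0.66 (interval 0.52 to 0.80) and PRDM14 0.61 (interval 0.09 to 1.13). The list had a median log2 ratio of 0.03 (interval -0.18 to 0.55), or 0.14 relative to all genes, at the 89.9th percentile of 10000 random lists matched on expression, which is a description of these libraries.

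Neuroectoderm genes had the lowest median of the lists with at least 3 measured members in the kept cells. Of 17 measured members, 11 were at least 1.5-fold lower in the KO library and 0 were at least 1.5-fold higher. Beside NR2F1 and STMN2, NR2F2 had a log2 ratio of -2.45 (interval -3.38 to -1.64), DACH1 -2.49 (interval -3.50 to -1.62) and MEIS2 -2.44 (interval -3.36 to -1.63). TUBB3 and LHX2 were within 1.5-fold, at log2 ratios of -0.07 and 0.13. The list median was -2.30 (interval -2.49 to -0.43), or -2.18 relative to all genes, below all of the 10000 random lists. With members of at least 20 CPM alone, the median was -0.91, so its size depends on which members are counted. Within clusters 1 to 4 of the cells, described with the cluster shares, it was -2.12, -0.25, -1.32 and -2.17, and the measured members can differ between clusters. Its intervals in cluster 2 (-3.98 to 1.09) and cluster 4 (-2.76 to 0.11) included 0. In cluster 2 members went both ways: NR2F1 (-3.98, interval -9.34 to -1.37) and STMN2 (-1.48, interval -2.71 to -0.40) were lower, while the upper end of the list's interval was 1.09. WNT targets had medians of -1.16, -0.85, -0.81 and -1.39 in clusters 1 to 4. Their interval lay below 0 in cluster 2 (-3.49 to -0.40) and included 0 in cluster 3 (-3.52 to 0.07).

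The primed-state list had a median of -0.35 (interval -0.67 to 0.04), or -0.24 relative to all genes, with 7 of 20 members at least 1.5-fold lower and 2 at least 1.5-fold higher. NEFM, a neurofilament gene, had a log2 ratio of -1.25 (interval -1.46 to -1.05), CRABP1, a retinoic acid binding protein gene, -0.92 (interval -1.03 to -0.81), and DUSP6, a phosphatase that acts on ERK, -0.84 (interval -1.01 to -0.68). PLAAT3 was higher, at 1.02 (interval 0.79 to 1.26).

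Among targets of signalling pathways, all 8 measured WNT targets were lower in the KO library, 6 of them by at least 1.5-fold, with a list median of -1.18 (interval -3.45 to -0.18), or -1.06 relative to all genes, that lay below all of the 10000 random lists. APCDD1 had a log2 ratio of -1.68 (interval -2.45 to -0.99), CCND1, the cyclin D1 gene, -1.27 (interval -1.49 to -1.05) and the receptor FZD7 -0.45 (interval -0.66 to -0.23). Of 14 FGF and ERK targets, 6 were at least 1.5-fold lower and 1 at least 1.5-fold higher, with a median of -0.40, at the 0.94th percentile. NODAL and TGF-beta targets went both ways, with 4 of 9 at least 1.5-fold lower and 1, TDGF1, at least 1.5-fold higher, around a median of 0.09 (interval -0.92 to 0.36) that was -0.28 at a minimum of 500 UMIs.

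Epithelial junction genes lay at the other end, with 7 of 17 measured members at least 1.5-fold higher in the KO library and 0 at least 1.5-fold lower. The list median was 0.35 (interval 0.16 to 0.84), or 0.47 relative to all genes, above all of the 10000 random lists. It was 0.58 at a minimum of 500 UMIs and, at minimums chosen after seeing the data, 0.63 at 250 UMIs, where 10 members were at least 1.5-fold higher, and 0.58 at 100 UMIs. Beside CDH1 and CLDN7, EPCAM, an epithelial adhesion molecule, had a log2 ratio of 0.84 (interval 0.68 to 1.01) and ESRP1, an epithelial splicing regulator, 0.87 (interval 0.58 to 1.17). In the mesenchymal and matrix list, 7 of 13 members were at least 1.5-fold lower and 0 at least 1.5-fold higher, with a median of -0.62 (interval -1.62 to -0.20), or -0.50 relative to all genes, that was -0.32 with members of at least 20 CPM alone. ZEB1 and ZEB2, repressors of CDH1, had log2 ratios of -2.05 (interval -2.95 to -1.24) and -1.85 (interval -2.55 to -1.21), and CDH2, the neural cadherin, -1.22 (interval -1.52 to -0.94).

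**Figure D2:**
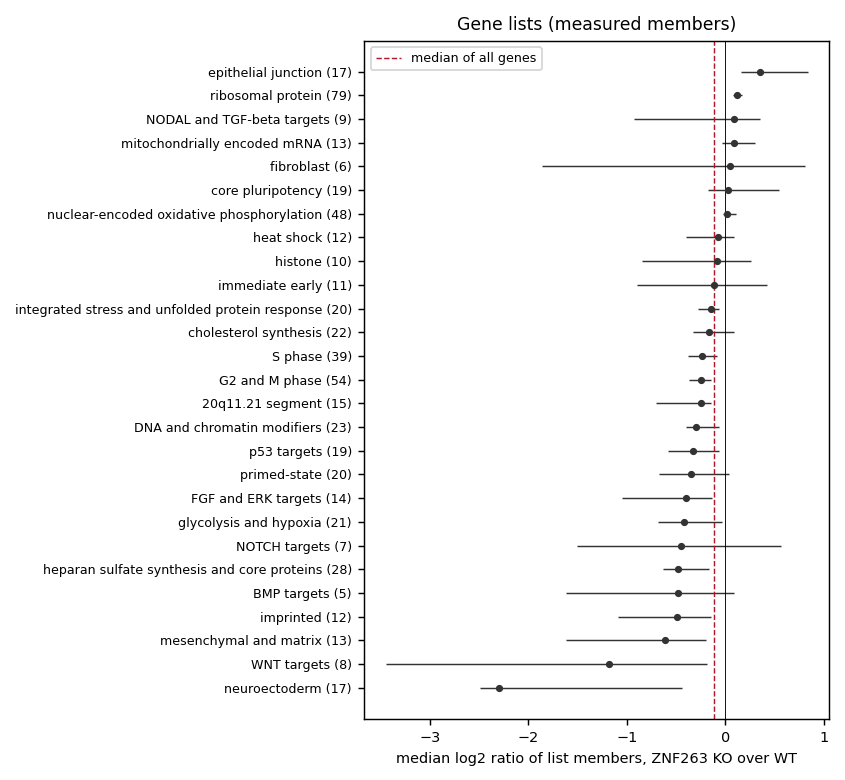
Median log2 ratio of KO over WT (horizontal axis) for each gene list with at least 3 measured members (vertical axis, number of measured members in brackets), with 95% order-statistic intervals over members. The dashed line is the median of all genes, -0.12; neuroectoderm lies lowest at -2.30 and epithelial junction highest at 0.35.

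The series was designed to compare the heterogeneity of both populations, so the next comparison was of single cells that carried transcripts of early lineages. At 1000 UMIs per cell, 51.0% of WT cells (interval 49.2% to 52.8%) and 36.7% of KO cells (interval 34.7% to 38.7%) held at least 1 UMI of the neuroectoderm list. For the primitive streak list the shares were 4.94% (interval 4.18% to 5.79%) and 1.53% (interval 1.07% to 2.12%). Its measured members, EOMES and MIXL1, both transcription factors of the streak, had log2 ratios of -1.81 (interval -2.69 to -1.01) and -1.38 (interval -2.09 to -0.73). Mesoderm transcripts were in 6.68% of WT and 4.72% of KO cells, and endoderm transcripts in 4.36% and 3.41%, where the interval of the log2 ratio of shares, -0.77 to 0.05, included 0. Amnion and trophoblast transcripts were in 2.45% and 2.10% of cells and naive-state transcripts in 1.09% and 0.919%, differences that were not detectable at this depth. Whether the mesoderm, endoderm, amnion and trophoblast, and naive-state intervals included 0 depended on the cell filter or thinning depth, and so did that of primitive streak, which was -2.01 to 0.40 at a minimum of 2000 UMIs. Without thinning, the shares in WT and KO were 63.7% and 47.9% for neuroectoderm, 7.19% and 2.14% for primitive streak, 9.23% and 6.87% for mesoderm, 6.71% and 5.56% for endoderm, 3.68% and 3.50% for amnion and trophoblast, and 1.67% and 1.49% for naive-state.

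The pooled profile of barcodes with 10 to 100 UMIs would by itself give neuroectoderm shares of 58.3% in WT and 39.9% in KO and primitive streak shares of 6.70% and 1.91%, above those seen. It would give 8.79% and 4.64% for mesoderm, where the KO share of 4.72% had an interval of 3.89% to 5.68%, 5.33% and 4.14% for endoderm, 2.83% and 2.24% for amnion and trophoblast, and 1.26% and 0.979% for naive-state. That profile correlated across genes with the kept cells of its library at 0.995 on the log2 scale in both libraries, so free RNA and shallow cells could not be separated. Whether these UMIs came from the cells or from free RNA is open, and the shares are not counts of lineage cells. Cells with at least 2 primitive streak UMIs were above that expectation, at 0.647% of WT cells (19 cells, interval 0.390% to 1.01%) against 0.229% and 0.131% of KO cells (3 cells, interval 0.0271% to 0.383%) against 0.0184%. With at least 2 UMIs neuroectoderm was not above it, at 19.9% of WT cells (interval 18.4% to 21.4%) against 21.8% and 9.19% of KO cells (interval 8.03% to 10.4%) against 9.30%, and for mesoderm it lay within the intervals, at 0.545% of WT cells (interval 0.312% to 0.884%) against 0.397% and 0.219% of KO cells (interval 0.0711% to 0.510%) against 0.109%.

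**Figure D3:**
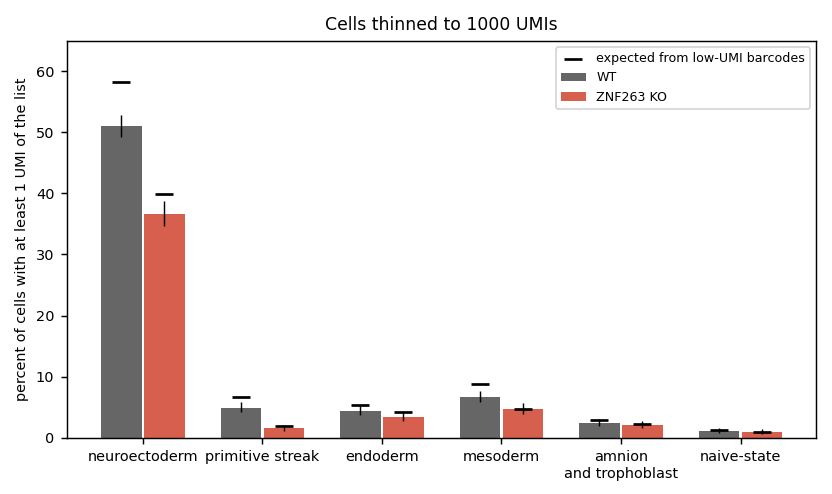
Percent of kept cells, each thinned to 1000 UMIs, with at least 1 UMI of each lineage list (vertical axis) in the WT (grey) and KO (red) libraries, with exact binomial 95% intervals. Black marks are the share expected from the profile of low-UMI barcodes; the neuroectoderm bars stand at 51.0% and 36.7%.

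Cell-to-cell variability was compared as variance over mean of thinned UMI counts in 1470 genes. Its median was 1.04 in WT and 1.03 in KO, and the median log2 ratio of KO over WT was -0.010 (interval -0.015 to -0.006). That interval included 0 in cells thinned to 500 UMIs (-0.0063 to 0.0032), for genes with a mean of at least 0.5 UMI (-0.024 to 0.0027) and at a minimum of 250 UMIs with thinning to 250 (-0.0030 to 0.0015), the last chosen after seeing the data. CRABP1 had the largest difference, at 2.82 in WT and 1.02 in KO, followed at the same end by MIAT, a long noncoding RNA, at 2.15 and 1.25, the growth factor gene PTN at 1.67 and 1.23, the tropomyosin gene TPM1 at 1.52 and 1.21, and CALD1 at 1.33 and 1.11. MIAT differed little in its level, with a log2 ratio of 0.13 (interval -0.00 to 0.25). At the other end were MT-ND3 (1.67 and 2.06), ACTB (1.06 and 1.24), MT-ATP6, MT-RNR2 and MT-ND1, which were also more abundant in the KO library. Among list sums, neuroectoderm was at 1.39 and 1.13 and core pluripotency at 1.51 and 1.28, while heat shock was at 1.46 and 1.57, S phase at 1.23 and 1.29 and mitochondrially encoded mRNA at 16.8 and 17.7. CRABP1 and the neuroectoderm sum (means of 0.814 and 0.485 UMIs) were also less abundant in the KO library, so their lower variability was not separated from their lower level. The core pluripotency sum was more abundant there (5.26 and 5.96 UMIs). At that minimum of 250 UMIs, core pluripotency was at 1.066 and 1.072 and neuroectoderm at 1.04 and 1.03. At a minimum of 2000 UMIs the log2 ratios of heat shock, S phase and mitochondrially encoded mRNA were -0.07, -0.07 and -0.12, the opposite direction.

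The cells of both libraries fell into 4 clusters, none of which was led by at least 3 markers of a fixed cell type list, so they keep numbers. Cluster 1 (led by ANKRD1, COL11A1, TENM3, ANXA1 and CADM1) held 44.9% of WT and 48.5% of KO cells, cluster 2 (BNC2, RBM7, PDLIM1, AP1M2 and TOX) 30.3% and 25.5%, cluster 3 (RPL36AP8, SYNGR1, MT-ND3, COX17P1 and P3H3) 14.3% and 16.9%, and cluster 4 (ODR4, LOC107985661, PHYKPL, ZNF785 and SNHG12) 10.5% and 9.06%. Median mitochondrial shares were 5.03%, 1.28%, 7.83% and 6.46%, and cluster 4 had a median of 2743.5 UMIs. Clustering without the genes that differed at least 2-fold between the libraries, an alternative chosen after seeing the data, gave shares of 45.7% and 50.8%, 32.2% and 27.5%, 11.7% and 12.6%, and 10.4% and 9.10%. Differences in share depended on the cells and settings used. Cluster 2 was lower by 4.74 points in the KO library (-4.74, interval -7.20 to -2.27). The second largest cluster differed by -4.42 points at a mitochondrial limit of 10%, -4.24 with equal cell numbers and -6.25 with doublets removed. It differed by 4.49 at a minimum of 500 UMIs, 2.38 at resolution 0.8 and 4.45 with 15 components, where it need not hold the same cells. Cluster 3, higher by 2.62 points in the KO library here (interval 0.609 to 4.65), differed by 0.238 points (interval -1.67 to 2.17) at a mitochondrial limit of 10% and by -0.744 (interval -2.81 to 1.32) with equal cell numbers, where clusters numbered by size need not hold the same cells. The largest cluster, higher by 3.60 points here (interval 0.842 to 6.35), differed by -2.82 (interval -3.94 to -1.70) at a minimum of 500 UMIs. At a minimum of 2000 UMIs there were 3 clusters, the interval of each difference in share included 0, and the distance between cluster shares was 3.62 percentage points against 6.22 here and 2.81 between random parts of the WT cells, which held more cells (1467 in the smaller part).

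Cell cycle phase was read from S and G2/M list scores of thinned cells. G2/M was assigned to 45.7% of WT cells (interval 43.9% to 47.5%) and 39.2% of KO cells (interval 37.2% to 41.2%), S to 50.1% and 53.1%, and G1 to 4.19% and 7.66%. Another thinning draw of the same cells moved these shares. It gave G2/M shares of 52.5% in WT and 45.3% in KO, each outside its interval above, and S shares of 43.6% and 48.4%. The shares are thus not levels of the cells, and their intervals leave out the thinning draw. The difference in G2/M was -6.53 percentage points (interval -9.24 to -3.80) and, in that other draw, -7.15 (interval -9.90 to -4.39). Random draws of control genes were combined with a smaller number of thinning draws, the main one among them. Over these 15 combinations the G2/M difference ranged from -8.56 to -3.20 and the S difference from 1.87 to 6.11. The G1 difference ranged from 0.837 to 3.35, all below the 3.46 points from all genes of a bin. At a minimum of 2000 UMIs, which left 513 WT and 366 KO cells, the G2/M difference was -3.92 points (interval -10.7 to 2.94), the G1 difference 3.29 (interval -0.561 to 7.38) and the S difference 0.636 (interval -6.15 to 7.44), all with intervals that included 0. The interval of the S difference also included 0 in cells thinned to 500 (-1.57 to 3.95) and 2000 UMIs (-3.41 to 10.1). The phases are ranges of a score, 3.37% of WT and 5.47% of KO cells lay near its limit, and free RNA enters the score in both libraries. G1 shares also moved with depth, so they are not levels of the cells. They were 9.34% in WT and 13.9% in KO cells thinned to 500 UMIs, and 0.971% and 5.08% thinned to 2000. Of 54 measured G2 and M phase genes, 9 were at least 1.5-fold lower in the KO library and 0 at least 1.5-fold higher, among them LBR at a log2 ratio of -0.75 (interval -0.99 to -0.52) and TTK at -0.70 (interval -0.95 to -0.46).

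Copy number was looked at through the median log2 ratio of each autosome. The medians ran from -0.21 on chromosome 21 (56 genes, interval -0.34 to -0.03) to -0.06 on chromosome 19 (360 genes, interval -0.10 to -0.02), around -0.12 for all genes. In the 20q11.21 segment, which is recurrently gained in human pluripotent cell lines, 1 of 15 measured genes, DNMT3B, was at least 1.5-fold higher in the KO library and 4 were at least 1.5-fold lower, among them ASXL1 at a log2 ratio of -1.43 (interval -1.87 to -0.998).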

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

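Barcodes that the comparisons do not use held 92.3% of the WT UMIs and 93.5% of the KO UMIs, a signal in barcodes outside the main measurement. In barcodes with at least 250 and fewer than 1000 UMIs (56837 in WT and 50551 in KO), log2 ratios of KO over WT correlated at 0.89 with those of the kept cells across 5573 genes, which are not independent replicates. With 1 library per genotype, no library was set against others of its group and no contrast against another.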

How the results depend on the processing

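Alternatives at 250 or 100 UMIs, those changing the UMI minimum and thinning depth together, another thinning draw, random control genes and clustering without differing genes were chosen after seeing the data. No list median, lineage share ratio or cell cycle difference whose interval excluded 0 changed sign. Cluster shares did. The largest cluster was higher by 3.60 points in the KO library (interval 0.842 to 6.35) and lower at a minimum of 500 UMIs (-2.82 points, interval -3.94 to -1.70). Clusters numbered by size need not hold the same cells. For the 12 highest and 12 lowest genes the naming rule fixed the sign under the planned scalings and cell filters, so those values say nothing of stability. Of the 105 values of named genes that it did not fix, 104 kept their sign, and NANOG was -0.10 at a minimum of 2000 UMIs. ZNF263 and the core pluripotency, primed-state and neuroectoderm medians stayed within their intervals, and so did the chromosome range; ZNF263 ran from -1.37 to -0.77 and the neuroectoderm median from -2.33 to -0.91. The core pluripotency median was below 0 at a minimum of 2000 UMIs (-0.04) and with members of at least 20 CPM (-0.05). Other medians whose intervals included 0 changed sign too: NODAL and TGF-beta targets at minimums of 500 (-0.28), 250 (-0.27) and 100 UMIs (-0.26), a mitochondrial limit of 10% (-0.05), with doublets removed (-0.03) and equal cell weight (-0.05), immediate early at 2000 UMIs (0.08) and by median-of-ratios scaling (0.0043), heat shock (0.05) and histone (0.03) by that scaling, histone at 100 UMIs (0.02), mitochondrially encoded mRNA at 250 (-0.00059) and 100 UMIs (-0.0043), and fibroblast in 5 alternatives (-0.39 to -0.20). At a minimum of 250 UMIs the mesoderm list had 3 measured members and a median of -2.42, below the -1.98 of neuroectoderm. The width of log2 ratios, 1.32, was 1.59 at 2000 UMIs, 1.24 at both 250 and 100 UMIs (1.242 and 1.240), 1.45 without mitochondrial and ribosomal protein genes in the totals, 1.87 at a mean of 5 CPM and 1.11 at 50 CPM. The log2 ratio of neuroectoderm shares, -0.47, was -0.62 and -0.25 in cells thinned to 500 and 2000 UMIs, -1.11 with at least 2 list UMIs, and -0.60 and -0.71 at minimums of 500 and 250 UMIs thinned to as many. Primitive streak, -1.69, was -0.74 at a minimum of 2000 UMIs and -2.30 with 2 list UMIs. Endoderm, -0.35, was 0.41 at a minimum of 2000 UMIs and 0.42 thinned to 2000. Mesoderm, -0.50, was -1.01 at a minimum of 2000 UMIs, -1.32 with 2 list UMIs, and -0.88 at both lower minimums (-0.882 and -0.875). The mesoderm interval included 0 with no mitochondrial limit (-0.62 to 0.04), equal cell numbers (-0.67 to 0.06), 2 list UMIs (-3.08 to 0.14) and thinned to 500 (-0.84 to 0.13) or 2000 (-0.88 to 0.38). The endoderm interval lay below 0 with no mitochondrial limit (-0.85 to -0.04), doublets removed (-0.93 to -0.08) and at minimums of 500 (-0.47 to -0.03) and 250 UMIs (-0.43 to -0.12). At 500 UMIs so did amnion and trophoblast (-0.60 to -0.0014) and naive-state (-0.95 to -0.02), and at 250 the former (-0.44 to -0.02). With 2 list UMIs, endoderm, amnion and trophoblast, and naive-state gave no ratio, because no KO cell held them. The variability ratio, -0.010, was -0.022 at a minimum of 2000 UMIs, -0.0041 with equal cell numbers, -0.0023 and -0.025 thinned to 500 and 2000, and -0.0055 and -0.00042 at minimums of 500 and 250 UMIs. The G1 difference, 3.46 points, was 2.13 with doublets removed and 0.837 to 3.35 over the 15 combinations of thinning and control gene draws. The distance between cluster shares, 6.22 points, was 3.62 and 4.53 at minimums of 2000 and 500 UMIs, 12.5 at resolution 0.8 and 21.7 with no centring by library. Of other results, 15 values under planned and 4 under added alternatives moved beyond their intervals, each with its direction kept. The cause was not tested.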

Other observations

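Of the tests in this part, those on the choice of barcodes and on leaving out CRABP1-rich cells were chosen after the result was seen. Of 12 measured imprinted genes, 11 were lower in the KO library and 4 by at least 1.5-fold, with log2 ratios of -1.12 (interval -1.28 to -0.96) for PEG10, -0.92 (interval -1.09 to -0.75) for NNAT and -0.58 (interval -0.96 to -0.21) for DLK1. In the glycolysis and hypoxia list, 6 of 21 genes were at least 1.5-fold lower and 0 at least 1.5-fold higher, with a median of -0.42. BNIP3 had a log2 ratio of -1.31 (interval -1.65 to -0.99), the glucose transporter gene SLC2A1 -0.77 (interval -1.01 to -0.54) and the pyruvate kinase gene PKM -0.74 (interval -0.86 to -0.63). In heparan sulfate synthesis and core proteins, 10 of 28 genes were at least 1.5-fold lower and 3 at least 1.5-fold higher, with SULF1, an extracellular sulfatase, at -1.79 (interval -2.49 to -1.14) and the glypican gene GPC1 at -1.27 (interval -1.82 to -0.75). Of 7 NOTCH targets, 3 were at least 1.5-fold lower, HES1 among them at a log2 ratio of -1.07 (interval -1.35 to -0.80), and 4 were within 1.5-fold, with a list median of -0.45 (interval -1.50 to 0.57). Of 5 BMP targets, 2 were at least 1.5-fold lower, ID2 among them at -0.85 (interval -1.10 to -0.60), and 3 were within 1.5-fold, with a median of -0.48 (interval -1.62 to 0.09). Ribosomal protein genes had a median of 0.11 (interval 0.08 to 0.17), with 59 of 79 higher and 79 within 1.5-fold. ACTB, a cytoskeletal actin gene with many pseudogenes, was 2.02-fold higher in the KO library (interval 1.96 to 2.08).

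Among the other lists, 4 of 19 p53 targets were at least 1.5-fold lower in the KO library and 0 at least 1.5-fold higher, with a median of -0.33 (interval -0.58 to -0.07), and DNA and chromatin modifiers had a median of -0.29 with 21 of 23 within 1.5-fold. The S phase median was -0.23, with 36 of 39 within 1.5-fold. Cholesterol synthesis (-0.17), the integrated stress and unfolded protein response (-0.15), immediate early genes (-0.11), histones (-0.08) and heat shock genes (-0.07) had medians between the 23.7th and the 66.8th percentile of matched random lists, and by median-of-ratios scaling those of immediate early, histone and heat shock genes were above 0 (0.0043, 0.03 and 0.05). Nuclear-encoded oxidative phosphorylation genes had a median of 0.02, with 48 of 48 within 1.5-fold, and mitochondrially encoded mRNAs 0.09, with 12 of 13 within 1.5-fold. Fibroblast markers went both ways, with 2 of 6 at least 1.5-fold higher and 2 at least 1.5-fold lower.

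A small set of WT cells was rich in CRABP1: at 1000 UMIs per cell, 28 of 2935 WT cells (0.954%, interval 0.635% to 1.38%) held at least 6 CRABP1 UMIs, and 0 of 2286 KO cells did, which allows a share of up to 0.131% as 3 counts of the total (exact interval up to 0.161%). In those cells NEFM was 15.4-fold (interval 12.4 to 18.9) and NR2F1 10.1-fold (interval 5.78 to 16.7) higher than in the other WT cells and, of 7 pluripotency genes looked at, L1TD1 was 2.63-fold (interval 1.77 to 4.11), LIN28A 1.52-fold (interval 1.01 to 2.41) and TDGF1, on 1 UMI, 6.55-fold lower (interval 1.17 to 259), while the intervals of SOX2 (1.14-fold, 0.651 to 1.86), DPPA4 (0.781-fold, 0.462 to 1.24), PODXL and DNMT3B included 1, genes chosen after their values were seen. Fewer or shallower KO cells are argued against by separate barcodes with at least 500 and fewer than 1000 UMIs, thinned to 500, where 157 of 13525 in WT (1.16%, interval 0.987% to 1.36%) and 3 of 11926 in KO (0.0252%, interval 0.0052% to 0.0735%) held at least 3 CRABP1 UMIs. An upper tail of CRABP1 in otherwise like cells is argued against by the neuroectoderm list, which was 2.22-fold higher (interval 1.92 to 2.55) in those WT barcodes than in the others. A candidate explanation, as a hypothesis, is a neural-like minority of WT cells: in barcodes with at least 250 and fewer than 500 UMIs, the 84 WT barcodes with at least 3 CRABP1 UMIs of 250 held 2.07-fold (interval 1.55 to 2.71) the neuroectoderm and 0.637-fold (interval 0.515 to 0.778) the core pluripotency UMIs of the others, and whether its rarity in the KO library follows from ZNF263, the clone or the culture was not tested and would need several clones and cultures per genotype.

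The 12 lowest genes had a median log2 ratio of -2.36. Loss of transcripts of secreted and membrane proteins from the KO library is argued against by 59 housekeeping genes of that kind, whose median relative to all genes was 0.0437 (interval -0.02 to 0.12). A dependence on the UMI minimum is argued against by barcodes with at least 250 and fewer than 500 UMIs, outside every cell filter of the naming rule, where the median was -2.17. Such barcodes can hold free RNA of the same library, so they are not a separate sample of cells. The 28 CRABP1-rich WT cells as the only source are argued against by the median of -2.28 without them. Neural-like WT cells with fewer CRABP1 UMIs were not left out, so that median does not address them. With 1 library per genotype, the effect of the ZNF263 genotype cannot be told apart from differences between clones, cultures or library preparations.

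The clusters may reflect which part of a cell's RNA a barcode holds. The same 59 housekeeping genes of secreted and membrane proteins had a median log2 ratio of 0.457 (interval 0.36 to 0.59) in cluster 1 over the other cells, with 54 of them higher, a direction written down before it was measured. Depth stays open: thinning each cell to 1000 UMIs before clustering gave 3 clusters with an adjusted Rand index of 0.417 against those reported, between the bounds set for and against it. No biological explanation was tested for this pattern.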
